A study of Mus musculus with 4 samples.

How the data were processed

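Testes were dissected away from the mesonephros of wild-type CD1 mouse embryos at stage E13.5, per the labels' protocols, and total RNA was taken from the frozen gonads. Stranded libraries depleted of ribosomal RNA were sequenced as paired 75 nt reads on a NextSeq500, per the labels. The depth the labels give is a target for each sample, not a count. There were 4 libraries, 1 in each of 4 groups. The groups were a control (titled Control, with the treatment labelled as none), acetaminophen (ACE+ACE), aspirin with acetaminophen (ASP+ACE) and ibuprofen with acetaminophen (IBU+ACE). The in-file name EtOH was matched to Control, the remaining library once the 3 drug names had been matched to their titles. Doses, days of exposure, and whether a library pooled several embryos are not given in the sources used here.

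The submitters' processing notes name bcl2fastq 2.17, FastQC, Bowtie2 2.2.6, TopHat2 2.1, SAMtools 1.3, Cufflinks 2.2.1 and the mouse genome GRCm38, without settings. The authors deposited 6 tables, 1 for each pair of libraries. Per the file headers, each row holds an assembled transcript, its locus, a gene name where one was assigned, the values of both libraries, the log2 fold change, a p-value and a q-value. The deposited values are taken as FPKM (fragments per kilobase of transcript, scaled to mapped fragments) from the layout of the tables, which is that of the Cufflinks suite; the file headers do not name the unit. The deposited log2 fold changes were the second library over the first and equalled the log2 recomputed from the 2 values within 1.09e-05.

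All 726 rows carried the status OK and were marked significant, so the authors' deposited tables hold called transcripts and no others. A transcript absent from a table may have been tested without a call or not tested at all. Every row had the same p-value of 5e-05 and the same q-value of 0.0310 in the authors' deposited tables, so neither can rank transcripts. If the 726 rows were every call of 1 Benjamini-Hochberg adjustment over the 6 comparisons, the q-value would stand for 449668 tests, or 74945 per comparison. Counts of reads were not used here, so the depth behind each value is unknown and no interval or detection floor is given. An exact 0 is reported only as listed at 0, with no fold change.

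The tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, with decimal commas turned into points, and plotted with matplotlib 3.10.9. No column was left unmatched to a library. Reading and counting were tested on 200 simulated rows with known values, of which 120 higher and 80 lower rows were recovered. Values of 1 library that occurred in more than 1 table were compared, and 0 disagreed. A total of 1093 of the 1528 possible values of 382 transcripts in 4 libraries could be read from the tables. Loci are given on GRCm38, counted from 1, after 1 was added to each start; 92 loci then equalled a gene of the GENCODE M21 annotation exactly, and 235 of 240 named transcripts had a symbol in it. Of the named loci, 81 span more than 1 annotated gene, and whether reads were assigned by strand is not given in the sources used here. Values of overlapping or antisense genes, and of genes with near-identical copies (histones, globins, ribosomal protein pseudogenes, small RNAs), are therefore uncertain.

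No test was run on the libraries, since 1 library per group gives no replicate check and p-values across genes would not replace one. The authors' calls compare libraries, not conditions. Transcripts were counted by direction, intersected between tables, and grouped by 23 gene lists fixed before the data were examined: Sertoli, Leydig and interstitial cell genes, germ cell pluripotency, male germ cell and meiosis genes, mitotic cycle genes, cyclin-dependent kinase inhibitors, histones, prostaglandin, retinoid and xenobiotic genes, ovarian, endothelial, macrophage, erythroid, mesonephros, liver, and neural or muscle genes, immediate early genes, mitochondrially encoded genes, small RNAs and sex-chromosome genes. A further 3 lists were written after the data had been seen: skin, cartilage and limb markers, further hepatic genes, and embryonic globins. The text names, for each comparison, up to 10 transcripts per direction with the highest absolute log2 fold change where the higher value was at least 1 FPKM, up to 3 per direction listed at 0 in 1 library, every listed member of a fixed list, and up to 10 transcripts listed in all 3 comparisons with the control. Some members of the erythroid list are not reported here and were left out of that list's counts and medians. Genes outside this rule are marked as chosen after their values were seen, unless the rule named them in another comparison. Alternatives were a q of 0.01 or less, an absolute log2 fold change of at least 1, a higher value of at least 1 FPKM, log2 fold changes after adding 1 or 0.1 FPKM, and leaving out small RNA genes; added after seeing the data were counts of named genes alone and counts without genes of other tissues. Chance overlap of comparisons that share the control library could not be simulated, because the tables hold called transcripts alone and 1 control library cannot be split.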

Results

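RNA was sequenced from testes of mouse embryos at stage E13.5, when male germ cells leave the pluripotent state and stop dividing and Sertoli cells have formed cords around them. The study asked how exposure in the womb to acetaminophen, aspirin or ibuprofen, the last pair given with acetaminophen, bears on the forming testis. Each of the 4 groups, Control, ACE+ACE, ASP+ACE and IBU+ACE, was represented by 1 library, so no difference has a replicate check and each comparison is between libraries. Levels are the authors' deposited values, read as FPKM, and the number of reads behind them is unknown. A gene is said to have risen or fallen only where the authors' deposited table lists it, with the same q of 0.0310 in all rows.

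The IBU+ACE library stood furthest from the rest. The authors' deposited tables list 185 transcripts between Control and IBU+ACE, against 67 for ACE+ACE and 44 for ASP+ACE. In IBU+ACE 151 were higher and 34 lower than in Control, whereas most transcripts listed for ACE+ACE (50) and for ASP+ACE (29) were lower. Between the exposed libraries, 232 transcripts separated ACE+ACE from IBU+ACE, 174 separated ASP+ACE from IBU+ACE, and 24 separated ACE+ACE from ASP+ACE. A set of 88 transcripts, 85 of them higher, set IBU+ACE apart from all 3 other libraries, against 12 for Control, 12 for ACE+ACE and 4 for ASP+ACE. Across the 6 tables the transcripts fall into 240 with a gene name, covering 235 genes, and 142 without one.

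**Figure D1:**
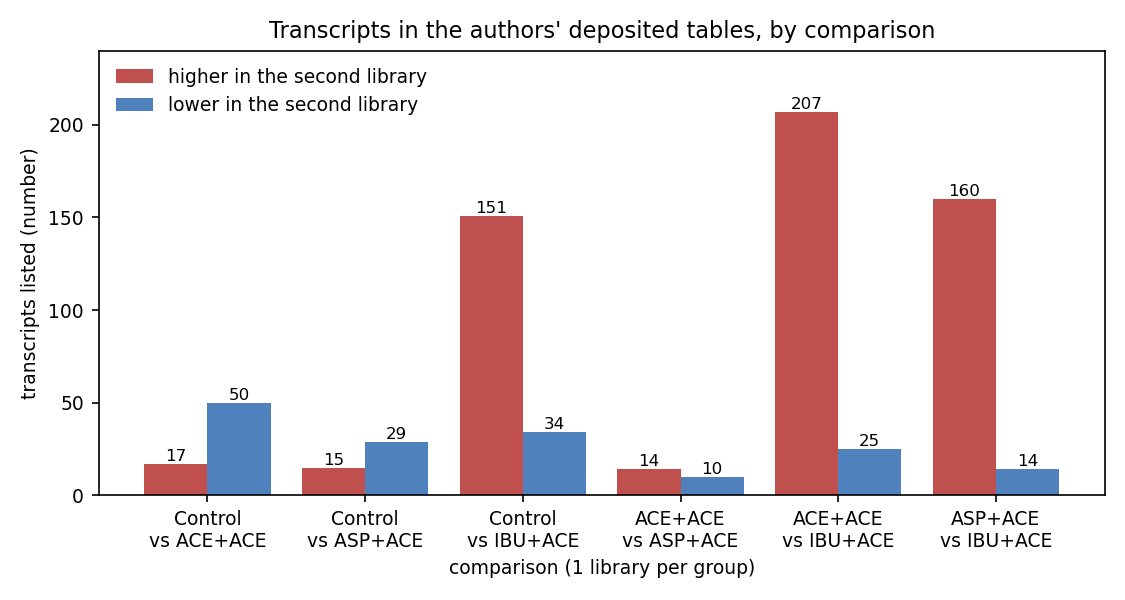
Number of transcripts (vertical axis) that the authors' deposited tables list as higher or lower in the second library of each comparison (horizontal axis, 1 library per group). The 3 comparisons with IBU+ACE hold the most transcripts, with 151, 207 and 160 higher in IBU+ACE.

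The comparison of Control with ACE+ACE shows which transcripts differed between the control library and the acetaminophen library, 1 of each. Genes made by the liver fell together in the ACE+ACE library. Of the 14 genes of the liver list, 7 fell and 0 rose, with a median log2 fold change of -1.78 in the authors' deposited table. Afp (alpha-fetoprotein; chromosome 5, 90490737 to 90515931) went from 130.2 to 34.2 FPKM, Alb (albumin; chromosome 5, 90460897 to 90476602) from 52.6 to 16.1 FPKM, and Apoa1, the main protein of high-density lipoprotein, from 18.3 to 5.03 FPKM. The other listed members were Apob, Ahsg, Fga and Fgb. A list of 33 further hepatic genes, written after the values were seen, added 12 that fell, so that 19 of the 34 named genes that fell were hepatic. Among them Trf (transferrin, also in the Sertoli list as a fetal Sertoli product) fell from 29.2 to 6.28 FPKM, Itih2 from 4.22 to 1.03 FPKM, Ambp from 5.91 to 1.53 FPKM and Spp2 from 2.18 to 0.50 FPKM.

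Red cell genes fell beside the liver genes in this library, with 2 of the 17 reported members of the erythroid list lower. Hbb-bt, an adult beta-globin gene, went from 595 to 293 FPKM, and Slc4a1, the red cell anion exchanger, from 15.5 to 7.35 FPKM. The metallothionein genes Mt1 and Mt2, which bind zinc and copper and are abundant in fetal liver, were the 2 listed members of the xenobiotic list; Mt1 fell from 29.9 to 13.9 FPKM and Mt2 from 16.3 to 6.42 FPKM. The embryonic myosin gene Myh3 fell from 4.46 to 1.85 FPKM. The 6 named genes that rose included 3 histone genes, with Hist1h4f at 142 FPKM in Control and 274 FPKM in ACE+ACE, Hist1h3f at 52.1 and 96.6 FPKM and Hist4h4 at 45.4 and 66.7 FPKM. The pseudogene Rps2-ps13 rose from 75.6 to 134 FPKM, and the pseudogene Gm14414 was listed at 0 in Control and at 1.80 FPKM in ACE+ACE; reads of both may belong to near-identical genes elsewhere. No member of the Leydig, pluripotency, male germ cell, meiosis, mitotic cycle or prostaglandin list appears in this table. After 1 FPKM was added to both values, 27 of the 67 transcripts had an absolute log2 fold change of at least 1, of which 3 were higher and 24 lower.

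**Figure D2:**
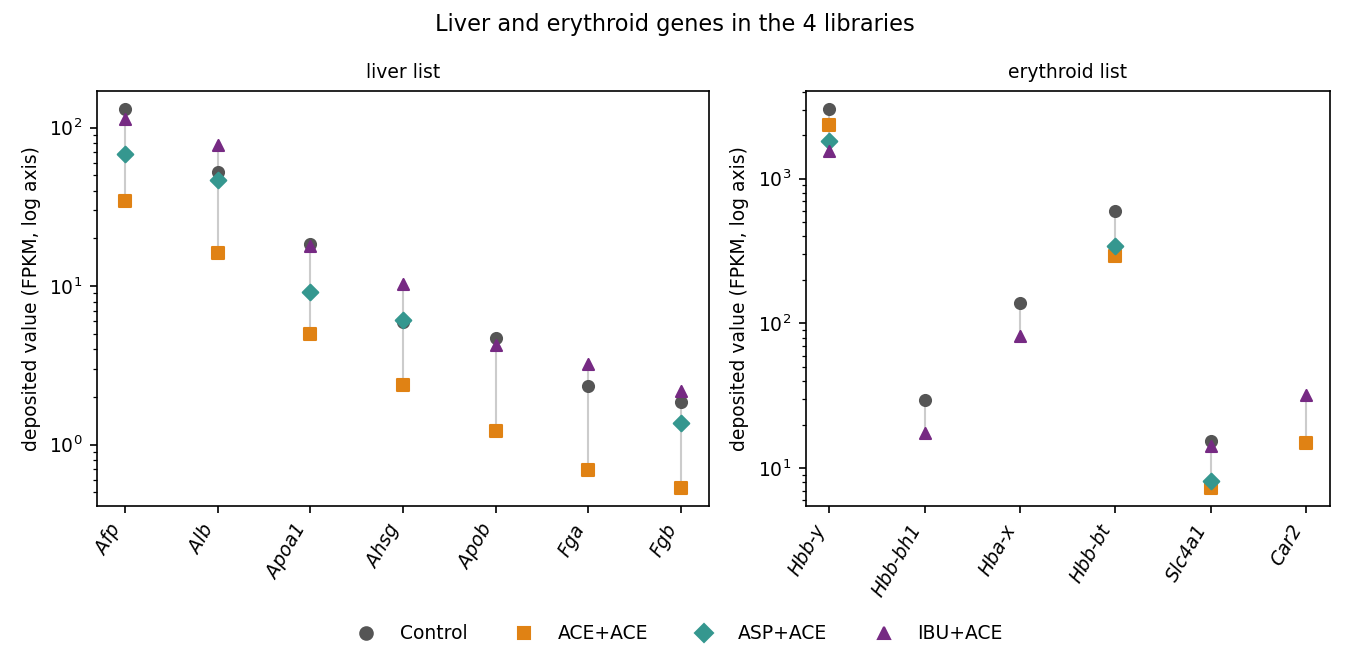
Deposited FPKM (vertical axes, log scale) of reported genes of the liver list (left) and the erythroid list (right) in each library, 1 symbol per library; a library without a symbol has no value for that gene in the tables. ACE+ACE has the lowest value of all 7 liver genes, from 34.2 FPKM for Afp to 0.536 FPKM for Fgb.

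In the comparison of Control with ASP+ACE, labelled aspirin with acetaminophen, liver and red cell genes again fell, 2 of the liver list and 3 of the erythroid list. Afp fell from 130.2 to 67.8 FPKM and Apoa1 from 18.3 to 9.20 FPKM, the 2 members of the liver list in this table, while Alb had 46.4 FPKM in ASP+ACE and was not listed against the control. Of the erythroid list, Slc4a1 fell from 15.5 to 8.15 FPKM, Hbb-bt from 595 to 345 FPKM and Hbb-y, a globin of embryonic red cells, from 3012 to 1809 FPKM. Myh3 fell from 4.46 to 2.41 FPKM. The cartilage collagen gene Col2a1 (chromosome 15, 97975602 to 98004703) fell from 2.92 to 1.10 FPKM. The histone genes Hist1h4f and Hist1h3f rose to 284 and 96.1 FPKM. Small RNA genes went both ways, with the snRNA gene Gm25360 up from 1351 to 2366 FPKM, the snRNA gene Gm22513 down from 843 to 351 FPKM and Gm24146 down from 7.62 to 1.25 FPKM. The long non-coding RNA Gm14230 rose from 1.84 to 6.46 FPKM. An unnamed transcript of chromosome X (135699267 to 135699356, 90 nt), outside annotated genes, had 709.8 FPKM in Control and was listed at 0 in ASP+ACE. For so short a transcript FPKM may not measure abundance. Germ cell, Sertoli, Leydig and prostaglandin lists had no member in this table. With 1 FPKM added, 17 of the 44 transcripts reached an absolute log2 fold change of 1, of which 3 were higher and 14 lower.

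The comparison of Control with IBU+ACE, labelled ibuprofen with acetaminophen, held germ cell genes. Of the pluripotency list 2 of 32 genes fell, and of the male germ cell list 2 of 38 rose. Lefty1 (chromosome 1, 180935022 to 180938400), an inhibitor of Nodal signalling expressed in germ cells before they differentiate, fell from 9.37 to 4.53 FPKM. Sox2, a core pluripotency factor, fell from 12.0 to 6.39 FPKM; its deposited locus (chromosome 3, 34104270 to 34682619) spans 15 annotated genes, so the value may include neighbours. Dnmt3l (chromosome 10, 78030022 to 78063622, a locus that also covers Aire), the cofactor of de novo DNA methylation in male germ cells, rose from 1.24 to 4.41 FPKM, with a log2 fold change of 1.83 in the authors' deposited table. Tdrd9 (chromosome 12, 111971484 to 112068854, a locus that also covers Rd3l), a helicase of the piRNA pathway that silences transposons, rose from 2.37 to 5.94 FPKM, a log2 fold change of 1.33 in the authors' deposited table. Sohlh2, a transcription factor of early germ cells, fell from 8.30 to 4.71 FPKM. Chosen after their values were seen, Tex15 rose from 11.9 to 19.9 FPKM and Morc1 from 8.84 to 14.2 FPKM, both needed for transposon silencing in male germ cells, and Podxl, a sialomucin, fell from 19.4 to 13.0 FPKM.

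The same IBU+ACE library carried much higher levels of a group of limb, cartilage and skin genes. Hoxd13 (chromosome 2, 74668310 to 74671599) went from 0.0680 to 11.0 FPKM and Hoxa13 (chromosome 6, 52257694 to 52260880) from 0.0961 to 9.13 FPKM, with log2 fold changes of 7.33 and 6.57 in the authors' deposited table; both pattern the most posterior and distal parts of the body. Gdf5, a joint and cartilage growth factor, rose from 0.159 to 5.25 FPKM, Col2a1 from 2.92 to 36.3 FPKM, the chemokine gene Cxcl14 from 0.855 to 12.9 FPKM, and Kera (keratocan) from 0.203 to 3.53 FPKM. The homeobox genes Msx1, Msx2, Irx1 and Irx5 rose as well, Msx1 from 0.788 to 12.7 FPKM, Msx2 from 0.603 to 2.31 FPKM, Irx1 from 0.121 to 2.52 FPKM and Irx5 from 0.20 to 2.41 FPKM. Msx1 and Msx2 stand in the meiosis list, and Irx5 and Bmp2, which rose from 0.979 to 2.09 FPKM, were the 2 listed members of the 15 ovarian genes; all 4 are also active in limb mesenchyme. Of 44 skin, cartilage and limb markers, a list written after the values were seen, 19 rose and 0 fell against Control, among them the epidermal keratin gene Krt5, from 1.27 to 7.35 FPKM. Xist, the RNA that coats the inactive X chromosome of female cells, went from 0.954 to 11.1 FPKM; its deposited locus (chromosome X, 103414467 to 103484957) also spans its antisense partner Tsix. No Y-linked member of the sex-chromosome list was in any table.

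Of the somatic cell lists, 2 of 36 Sertoli genes, 1 of 24 interstitial genes and 0 of 28 Leydig genes were listed in IBU+ACE against Control. Sox9, which drives Sertoli cell fate and is also a cartilage gene, rose from 5.98 to 10.04 FPKM and Cst9, a cystatin of fetal Sertoli cells, from 63.3 to 114 FPKM. The deposited locus of Cst9 (chromosome 2, 148820081 to 148838738) also covers Cst13, so its value may include that gene. Lum (lumican) rose from 11.3 to 18.6 FPKM in the interstitial list. The retinoic acid binding protein genes Crabp1 and Crabp2 rose from 5.03 to 13.3 FPKM and from 6.98 to 20.1 FPKM, the 2 listed of 18 retinoid genes. All 5 listed histone genes rose, with Hist1h4f at 296 FPKM, Hist1h3f at 104 FPKM, Hist4h4 at 78.7 FPKM, Hist2h4 up from 10.7 to 21.7 FPKM and Hist1h4h up from 297 to 432 FPKM. The 3 listed red cell genes were embryonic globins, and all fell: Hbb-y to 1557 FPKM, Hbb-bh1 from 29.5 to 17.4 FPKM and Hba-x from 138 to 82.3 FPKM. No liver-list gene was listed in this table. Over the 7 members with a value, log2 IBU+ACE over Control had a median of 0.250 and ran from -0.209 to 0.801. Afp had 130.2 FPKM in Control and 113 FPKM in IBU+ACE, Alb 52.6 and 77.3 FPKM, and Ahsg 5.90 and 10.3 FPKM. Among other genes that fell were Prl3b1, a placental lactogen, from 2.09 to 0.576 FPKM, and the pseudogenes Gm5611, from 2.64 to 0.602 FPKM, and Rps2-ps13, from 75.6 to 44.3 FPKM. The pseudogene Gm15181 was listed at 0 in Control and at 8.46 FPKM in IBU+ACE. With 1 FPKM added, 56 of the 185 transcripts reached an absolute log2 fold change of 1, of which 46 were higher and 10 lower.

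**Figure D3:**
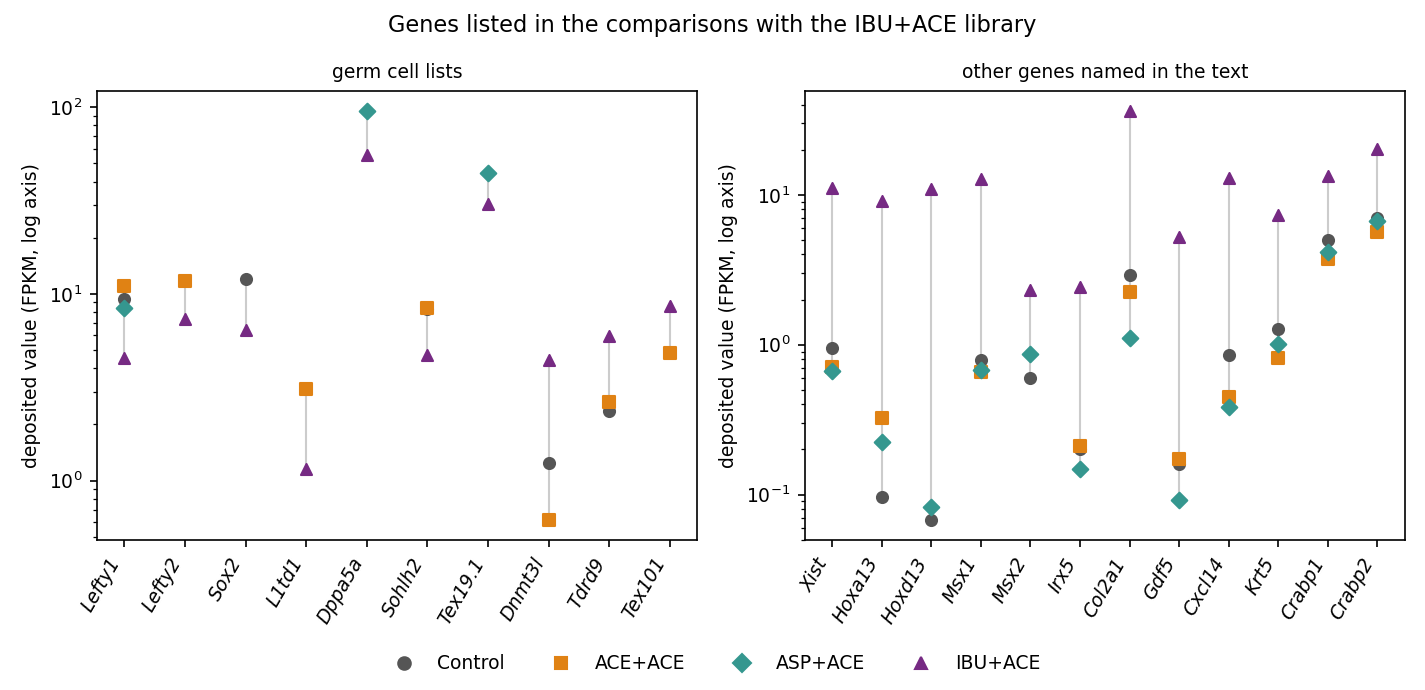
Deposited FPKM (vertical axes, log scale) in each library of germ cell genes (left) and of further genes named in the text (right), 1 symbol per library; a library without a symbol has no value for that gene in the tables. IBU+ACE has the lowest value of Lefty1 (4.53 FPKM) and the highest values of Dnmt3l (4.41 FPKM), Xist (11.1 FPKM) and Col2a1 (36.3 FPKM).

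Some transcripts were listed against Control in all 3 exposed libraries: 12, of which 4 were higher and 8 lower, and each went the same way throughout. Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366940 to 123462664), had 44.8 FPKM in Control, 5.72 in ACE+ACE, 11.8 in ASP+ACE and 6.28 in IBU+ACE. Alongside it fell 4 short unnamed transcripts outside annotated genes. The one with the highest FPKM (chromosome 1, 136364885 to 136364971, 87 nt) went from 11901 FPKM in Control to 1325, 2944 and 1175 FPKM. At that length, too, FPKM may not measure abundance. The other 3 lie on chromosome 1 (102628205 to 102628327), chromosome 6 (3201436 to 3201565) and chromosome 3 (5860338 to 5860774). Their sequences were not searched for repeats or ribosomal RNA, so what these transcripts are, and whether reads of the Lars2 locus come from its mRNA, is not known here. Over these 5 transcripts the log2 fold changes of the authors' deposited tables had medians of -2.97 for ACE+ACE, -1.93 for ASP+ACE and -2.84 for IBU+ACE. Chgb (chromogranin B) fell from 0.719 FPKM to 0.115, 0.0809 and 0.0759 FPKM, and the apolipoprotein gene Apoa4 from 1.74 FPKM to 0.438, 0.361 and 0.661 FPKM. Hist1h4f and Hist1h3f were the 2 named genes that rose in all 3. An unnamed transcript of chromosome 1 (35567633 to 35608435) rose from 0.0803 FPKM to 0.525, 0.758 and 1.11 FPKM, and another on chromosome X (105949694 to 105958216) fell from 0.912 FPKM to 0.0227, 0.305 and 0.173 FPKM.

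In pairs, 20 transcripts were shared between the control comparisons of ACE+ACE and ASP+ACE, 19 between ACE+ACE and IBU+ACE, and 19 between ASP+ACE and IBU+ACE. All 20 of the first pair and 18 of each other pair went the same way. Independent lists of these lengths among 74945 transcripts would share 0.0343 or fewer transcripts per direction. That figure leaves out the common control library, for which no value without an effect could be simulated, and part or all of the overlap may come from it. Of the 12 transcripts listed in all 3 tables, 9 were not listed between any exposed libraries.

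Between ACE+ACE and ASP+ACE, labelled acetaminophen and aspirin with acetaminophen, the genes that rose were largely hepatic. Of the 11 named genes higher in ASP+ACE, 8 belonged to the liver list or the further hepatic genes. Alb rose from 16.1 to 46.4 FPKM, Afp from 34.2 to 67.8 FPKM, Ahsg from 2.38 to 6.10 FPKM and Fgb from 0.536 to 1.37 FPKM. Serpina6 (corticosteroid-binding globulin), Gc (vitamin D binding protein), Vtn (vitronectin) and Ambp went the same way, as did Lars2, from 5.72 to 11.8 FPKM. Lower in ASP+ACE were the pseudogenes Rps2-ps13, from 134 to 61.1 FPKM, and Rpsa-ps10, from 193 to 119 FPKM, Gm43197, from 54.6 to 34.4 FPKM, and the snRNA gene Gm22513, from 703 to 351 FPKM. The table lists 14 transcripts as higher and 10 as lower. Leaving out the liver, skin, cartilage and limb genes left 6 higher and 10 lower, and 7 of the 24 transcripts reached an absolute log2 fold change of 1 with 1 FPKM added.

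Between ACE+ACE and IBU+ACE, 207 transcripts were higher in IBU+ACE and 25 lower. Lefty1, Sohlh2, Dnmt3l and Tdrd9 went the same way as against Control. Both comparisons use the same IBU+ACE library, and Sox2 was not listed here. Lefty1 fell from 11.0 to 4.53 FPKM, and its neighbour Lefty2 from 11.7 to 7.37 FPKM. L1td1, an RNA-binding protein of pluripotent cells, fell from 3.10 to 1.15 FPKM, and Sohlh2 from 8.37 to 4.71 FPKM. Foxh1, a partner of Nodal signalling, fell from 3.03 to 1.24 FPKM, and Thy1 from 1.07 to 0.30 FPKM. Dnmt3l rose from 0.619 to 4.41 FPKM, Tdrd9 from 2.64 to 5.94 FPKM and Tex101, a germ cell surface protein, from 4.83 to 8.67 FPKM, the 3 listed male germ cell genes. The limb, cartilage and skin genes were again higher, with Kera, Gdf5, Cxcl14 and Hoxa13 showing log2 fold changes of 5.59, 4.92, 4.85 and 4.82 in the authors' deposited table, and Xist went from 0.710 to 11.1 FPKM. Liver genes were higher too. All 7 listed members rose, with a median log2 fold change of 2.03 in the authors' deposited table, and Alb went from 16.1 to 77.3 FPKM. Of the 33 further hepatic genes 12 rose. Trf, Itih2, Spp2, Apom and Apoa4, which had fallen in ACE+ACE against Control, were not listed here. Of the erythroid list, Slc4a1 rose from 7.35 to 14.3 FPKM and Car2 from 14.9 to 32.2 FPKM, and Hbb-y fell from 2350.3 to 1557 FPKM. Mt1 and Mt2 rose to 30.1 and 16.6 FPKM, close to their Control values of 29.9 and 16.3 FPKM.

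Smaller groups in that table were Sox9, which rose from 5.97 to 10.04 FPKM, Bmp2 and Irx5 of the ovarian list, Crabp1 and Crabp2 of the retinoid list, Msx1 of the meiosis list, Lum of the interstitial list, and Hist1h4i, which rose from 41.3 to 74.6 FPKM. Vcam1, the 1 listed gene of 28 in the Leydig list, rose from 4.33 to 8.64 FPKM. The muscle genes Actc1 and Myh3 rose from 6.41 to 12.7 FPKM and from 1.85 to 4.54 FPKM. The deposited locus of Actc1 (chromosome 2, 114009601 to 114068324) also covers Gjd2 and other annotated genes, so its value may include neighbours. A 5813 nt transcript that carries the symbol Mir122 rose from 0.196 to 0.641 FPKM, and a 1759 nt transcript inside Fgf12 that carries the symbol Mir690 was listed at 0 in ACE+ACE and at 0.297 FPKM in IBU+ACE; neither value measures the microRNA itself. Requiring a higher value of at least 1 FPKM left 154 of the 232 transcripts, and 76 reached an absolute log2 fold change of 1 with 1 FPKM added.

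Between ASP+ACE and IBU+ACE, 160 transcripts were higher in IBU+ACE and 14 lower. Where the higher value was at least 1 FPKM, Hoxd13, Gdf5, Hoxa13, Cxcl14, Col2a1, Kera, Gabrp, Msx1, Xist and Irx5 had the highest finite log2 fold changes of the authors' deposited table, from 7.06 for Hoxd13 to 4.04 for Irx5. The 3 genes of the pluripotency and male germ cell lists in this table were all lower in IBU+ACE. Lefty1 fell from 8.41 to 4.53 FPKM, Dppa5a, an RNA-binding protein of pluripotent and early germ cells, from 95.5 to 55.4 FPKM, and Tex19.1, which guards germ cells against retrotransposons, from 44.6 to 30.4 FPKM. Neither Dnmt3l nor Tdrd9 was listed here. Sox9 rose from 5.22 to 10.04 FPKM, Vcam1 from 3.98 to 8.64 FPKM, Crabp1 from 4.13 to 13.3 FPKM and Crabp2 from 6.65 to 20.1 FPKM. Bmp2, Msx2 and the histone gene Hist3h2ba rose, the last from 17.8 to 29.9 FPKM. Afp, Alb and Apoa1 rose, Afp from 67.8 to 113 FPKM. The muscle genes Actc1, Myh3 and Myod1 rose, Myod1 from 0.360 to 1.15 FPKM, and so did Wnt7b, the 1 listed gene of 20 in the mesonephros list, from 0.187 to 1.03 FPKM. Evx2, the neighbour of Hoxd13, was listed at 0 in ASP+ACE and at 1.82 FPKM in IBU+ACE. The snRNA gene Gm22513 rose from 351 to 751 FPKM. Assembled transcripts of 11875 nt and 8833 nt that carry the symbols of the small RNA genes Gm24222 and Gm27507 were higher and lower, and their values are not those of the small RNAs. With 1 FPKM added, 57 of the 174 transcripts reached an absolute log2 fold change of 1.

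Several lists had 0 members in any of the 6 tables. These were the mitotic cycle list (32 genes), the cyclin-dependent kinase inhibitors (10), the prostaglandin pathway with both cyclooxygenase genes (30), endothelium (14), macrophages and other immune cells (18), the immediate early genes (19) and the mitochondrially encoded genes. Since the tables hold called transcripts alone, a gene's absence does not show that its level was equal in the libraries.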

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

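The tests in this part were chosen after the results had been seen. In 2 genes the libraries moved in opposite directions against Control, and the authors' deposited tables also list each gene between the exposed libraries in question, 1 library each. The pseudogene Rps2-ps13 (chromosome X, 52898588 to 52899469) had a log2 fold change of 0.83 in ACE+ACE and -0.77 in IBU+ACE in the authors' deposited tables, and -1.60 between them. Col2a1 (chromosome 15, 97975602 to 98004703) had a log2 fold change of -1.41 in ASP+ACE and 3.64 in IBU+ACE in the authors' deposited tables, and 5.04 between them.

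Col2a1 belongs to a wider pattern: Xist and genes of skin, cartilage and limb were higher in the IBU+ACE library than in every other library that gave them a value. A candidate explanation for the skin, cartilage and limb genes, though not by itself for Xist, is RNA from such tissue in that library. Of 44 such markers, 5 of which also stand in a fixed list, 21 were listed as higher there and 0 as lower, led by Col2a1 at 36.3 FPKM, Twist1 at 17.9 FPKM and Msx1 at 12.7 FPKM. The list was written after the values had been seen, and its members have a value only where called. The count can therefore neither exclude nor establish this explanation. An ovary among the gonads could account for Xist; 2 of the 15 ovarian genes, Bmp2 and Irx5, were listed as higher and 0 as lower, too few to decide, since both are also limb genes and the other 13 have no value here. With 1 library per group, tissue, sex of the embryos and an effect of ibuprofen stay open, the last untested.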

How the results depend on the processing

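The added counts of named genes and of genes without other tissues were chosen after seeing the data; the other alternatives were set before the data were examined. A q of 0.01 or less gave no value, since every transcript has q = 0.0310, and centring on uncalled genes was not run, since the tables hold called transcripts alone. No paired analysis was possible because each group has 1 library, which also rules out leaving a library out. With 1 FPKM added and an absolute log2 of at least 1 required, the counts moved to 27 and 17 transcripts for Control against ACE+ACE and ASP+ACE, 56 for Control against IBU+ACE, 7 for ACE+ACE against ASP+ACE, 76 for ACE+ACE against IBU+ACE and 57 for ASP+ACE against IBU+ACE; added FPKM shrinks the folds of low transcripts by construction. A higher value of at least 1 FPKM moved ACE+ACE against IBU+ACE to 154. Named genes alone, each counted once, gave 40 for ACE+ACE, 21 for ASP+ACE and 123 for IBU+ACE against Control. The remaining counts stayed within 1.5 times their value under the filters on fold, level, small RNAs and other tissues, and the majority direction turned in ACE+ACE against ASP+ACE alone, to 9 higher and 10 lower without the fixed lists of other cell types and to 6 and 10 without liver, skin, cartilage and limb genes. The overlap of the 3 control comparisons was 12 transcripts, and 9 with an absolute log2 of at least 1 or a higher value of at least 1 FPKM. Of 167 log2 fold changes of 83 named genes, 59 moved by more than 1.5-fold with 1 FPKM added and 17 with 0.1 FPKM added; adding a constant cannot turn a sign. Depth is unknown, so how far counting error alone moves the low values cannot be given.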

Other observations

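Some unnamed transcripts clustered within long genes. Zfhx3, a homeobox transcription factor gene (chromosome 8, 107942644 to 108961630), held 11 unnamed transcripts, of which 7 were higher in IBU+ACE than in Control, 8 higher than in ACE+ACE and 5 higher than in ASP+ACE, with 0 lower. Fgf12 (chromosome 16, 28160098 to 28753068) held 5, of which 2, 3 and 3 were higher in IBU+ACE. Their levels in IBU+ACE were at most 0.649 FPKM in Zfhx3 and 0.367 FPKM in Fgf12. Of the 142 unnamed transcripts, 114 overlapped no gene of the annotation. The one of these with the highest FPKM (chromosome 1, 122357128 to 122357249, 122 nt) had 17614 FPKM in Control and 33322, 29629 and 29288 FPKM in ACE+ACE, ASP+ACE and IBU+ACE. At such a length FPKM may not measure abundance. On chromosome 2 an unnamed transcript (77875529 to 77877360) had 1.98 FPKM in ASP+ACE against 8.86, 6.60 and 9.49 FPKM in Control, ACE+ACE and IBU+ACE.

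The tests below were chosen after the results had been seen. In the ACE+ACE library 7 of 14 liver-list genes were lower than in Control. The listed liver genes fell further than the 2 listed red cell genes, with medians -0.734 apart on the log2 scale. For these called genes that argues against a lower share of blood cells alone. It cannot decide the question for the rest of either list, which has no call here. Different amounts of liver RNA could give the pattern, but the SD of 0.215 of the 7 log2 ratios cannot decide it. These genes, led by Afp at 34.2 against 130.2 FPKM, have a value through being called, and the other 7 have none. The labels give dissection from the mesonephros, and whether liver was kept out is not known here. An acetaminophen effect alike in every exposed group stays open as well: the median log2 over Control was 0.250 for the same 7 genes in IBU+ACE and -0.43 for the 5 with a value in ASP+ACE, while Apoa4 was lower in all 3 exposed libraries, and liver RNA in a library would hide such an effect. An effect of acetaminophen that another drug offsets stays open and was not tested.

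In the IBU+ACE library 2 of 32 pluripotency genes, Lefty1 and Sox2, were lower than in Control and 2 of 38 male germ cell genes, Dnmt3l and Tdrd9, higher, while Tex19.1 of the latter list was lower than in ASP+ACE. Dilution of gonadal RNA by other tissue would by itself raise none of Dnmt3l and Tdrd9, with a median log2 of 1.58, or Tex15, Morc1 and Cst9, also listed as higher than in Control, but these genes were picked because they rose and most other germ cell genes have no value here; for Lefty1 and Sox2 it stays open, as the SD of 0.102 rests on 2 genes. Embryos somewhat further in development could give the pattern. The 3 embryonic globins, which decline with age, lay at a median of -0.649 on the log2 scale from Slc4a1. That gap cannot decide the question, as 1 other red cell gene is too few. The globins were also called lower than in Control and Slc4a1 was not, so the calls themselves favour such a gap. Hbb-y also fell in ASP+ACE, where no pluripotency gene was listed against Control. A change in germ cell differentiation through ibuprofen stays open as a biological explanation and was not tested.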
